A study of Mus musculus with 4 samples.

How the data were processed

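Total RNA from the inferior vena cava of wild-type and Cd39-null mice was extracted with Trizol, per the labels' protocols. The mice were 8 to 10 weeks old and had been crossed for at least 8 generations to C57BL/6J. The vein was ligated for 48 h or dissected without ligation (sham). The sources used here do not say which pools were male or female, which ligations were partial, or whether the clot was part of the RNA piece. From 50 ng of RNA, cDNA was amplified with a whole-transcriptome kit, and 3 µg of it was biotinylated and hybridised to an Affymetrix whole-transcript array. RNA of 4 mice was pooled for each of the 4 groups and each pool was run on 1 array, per the series' design text.

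The deposited values are log2 expression values per probe set, made by the authors with RMA in the package oligo, per the submitters' processing notes; versions are not given in the sources used here. RMA subtracts background, quantile normalises the arrays and summarises the probes of a probe set, so a global shift in RNA content between groups would be hidden in these values. They were used as deposited, with no further scaling. Scanner files were not used here. For arrays no read depth applies; the number of arrays limits the precision, and background limits what dim genes can show. As a stand-in for background, 1006 olfactory receptor probe sets had 95th percentiles of 2.94 log2 (wild type, sham), 2.66 (wild type, ligated), 2.97 (Cd39-null, sham) and 2.68 (the array labelled Cd39-null, ligated).

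Probe sets were named through the platform's annotation table. Of 35556 probe sets, 21218 carried 1 gene symbol, 1881 several and 12457 none. Symbols were compared through Entrez identifiers with a RefSeq table of assembly GRCm38.p6: 21185 matched, 33 did not, and 0 symbols had to be updated. That table was used only for names and for which genes neighbour Entpd1, since the sources used here name no genome build. For the 1386 of 18820 genes with several probe sets, the one with the highest mean log2 over the 4 arrays was taken. Genes were kept where that mean was at or above the 25th percentile (2.29), leaving 14115. Probe sets with no or several symbols entered no gene comparison other than the alternative limma fits on all probe sets; they count in the medians and correlations of whole arrays, and 4 hemoglobin probe sets with several symbols are given in the closing section.

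Comparisons were ligated against sham within each genotype, Cd39-null against wild type within each surgery, and the difference of the ligation differences. Each is a difference of log2 values between arrays with no test and no p-value, summarised by the number of genes at least 2-fold apart. The tests available were those of an additive model of genotype and ligation over the 4 arrays, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with matrixStats 1.5.0, and adjusted by Benjamini-Hochberg. This fit has 1 residual degree of freedom and a prior of 3.67, and it takes any difference between the genotypes' responses as error. No pool was replicated, so its p-values rest on how alike a difference was in both array pairs. The ligation differences of the genotypes share no array, and neither do the genotype differences of the surgeries.

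A total of 32 gene lists covered cell types that a piece of vein with or without clot could hold, pathways of inflammation, coagulation, matrix, metabolism, stress and proliferation, purinergic signalling, clock, ribosomal and sex linked genes, genes near Entpd1, and genes known to differ among C57BL/6 substrains and related strains. A list's median log2 difference was placed among 10000 random lists of the same size, matched on deciles of mean expression, and called apart outside the central 95%. This describes these arrays and is not a p-value across replicates. Counts of limma calls are given adjusted over the list alone and over all genes.

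Genes named in the report followed a rule. For ligation, they were the 12 highest and 12 lowest by mean difference among genes at least 2-fold apart in the same direction in both genotypes, with genes past the adjusted p taken ahead of others. For genotype, they were the 8 highest and 8 lowest among genes at least 1.5-fold apart in the same direction in both surgeries, and for the difference of ligation differences the 8 highest and 8 lowest. From each list up to 4 members with the largest mean ligation difference, and for genotype up to 4 with the largest mean genotype difference or difference of ligation differences, could be named, besides Entpd1 and the sex linked genes. Predicted, RIKEN, microRNA, small nuclear and nucleolar RNA, T cell receptor and immunoglobulin segment, olfactory and vomeronasal genes were left out of the rankings by the form of their symbols. Rmrp and Jchain, whose symbols have none of these forms, stayed in. In the closing section, Pf4, members of the 3 added lists, and immunoglobulin and small RNA genes were named outside this rule, after their values had been seen.

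The groups, comparisons, tests, thresholds, naming rule, lists and most alternatives were fixed before the data were examined. The alternatives were no filter or a filter at the 50th percentile of mean expression, the median over a gene's probe sets, quantile and cyclic loess normalisation, a 1.5-fold threshold, a trended or robust eBayes prior, all probe sets, the genotype comparisons without sex linked genes and genes near Entpd1, the mean in place of the median of a list, and lists without shared members. Chosen after the data were seen were wild type, sham, as the reference of the knockout comparison, the counts without genes of fat, B and plasma cells or of platelets and neutrophils, and 3 added lists of platelet, brown adipocyte and plasma cell genes. Spreads of list medians in the closing section are standard errors from resampling the list's genes. They hold no spread between arrays, pools or mice, and the genes of a list are not independent.

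The procedures were tested on simulated data. For the ligation effect over both genotypes, 14115 genes were simulated with spreads drawn from the fitted prior, 50 genes each differing by 1, 2, 3 and 4 log2. Of these, limma's adjusted test called 1, 43, 48 and 49, together with 9 of 13915 unchanged genes. With each gene's own posterior spread it called 21, 50, 50 and 50, together with 34 unchanged genes. With spreads from the prior, at least 2-fold in the same direction in both genotypes by chance were 79 of the unchanged genes, and 736 (5.29%) were at least 2-fold apart in the wild-type pair alone; with posterior spreads these were 21 and 244 (1.75%). For ligated against sham in wild type, 200 random lists of 15 genes stood apart in 2.5% of cases when unchanged and in 100% when shifted by 1 log2. The simulated genes varied independently, so 2.5% is not the rate for lists whose genes vary together, such as cell type markers.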

Results

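Gene expression was measured in the inferior vena cava of wild-type and Cd39-null mice, either 48 h after the vein had been tied off below the kidneys to provoke a stasis thrombus or after sham surgery. CD39, encoded by Entpd1, is a membrane enzyme of endothelial cells and leukocytes that breaks down extracellular ATP and ADP. Each of the 4 groups was represented by 1 array, hybridised with RNA pooled from 4 mice, so the difference between a pair of arrays has no replicate check and is given without a p-value. The number of arrays limits the precision of every value, and differences of genes that lie at or under the olfactory receptor background on an array are approximate in size and order. The sources used here do not say whether clot was part of the RNA pieces, whether ligation was complete or partial in these mice, or of which sex the pooled mice were. The arrays had median log2 values of 3.04 (wild type, sham), 2.99 (wild type, ligated), 3.03 (Cd39-null, sham) and 2.97 (labelled Cd39-null, ligated) over 35556 probe sets, and 14115 genes were kept for the comparisons. Across probe sets, which are not independent replicates, the ligated arrays had the highest Pearson correlation with each other (0.967), followed by the wild-type sham and ligated arrays (0.947) and the sham arrays (0.943), and the Cd39-null sham and ligated arrays had the lowest (0.917). Over the 14115 genes the ligated arrays were again first (0.939) and the Cd39-null arrays last (0.857), but the sham arrays (0.929) came before the wild-type arrays (0.915).

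The targeted gene Entpd1 was low on the Cd39-null array from sham surgery but not on the ligated one. Its log2 value was 7.11 in wild type, sham, 6.17 in wild type, ligated, 4.16 in Cd39-null, sham, and 6.14 on the array labelled Cd39-null, ligated. In sham veins it was thus 7.73-fold lower in the knockout, the third-lowest genotype difference of the 14115 genes, whereas in ligated veins the genotypes differed by -0.03 log2. The Entpd1 level therefore goes against the genotype label of the ligated Cd39-null array, which is called the array labelled Cd39-null, ligated, throughout. The single Entpd1 probe set covers a whole transcript cluster, and it is not known here whether it lies in the deleted part of the gene. Every direction that uses this array rests on its label.

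**Figure D1:**
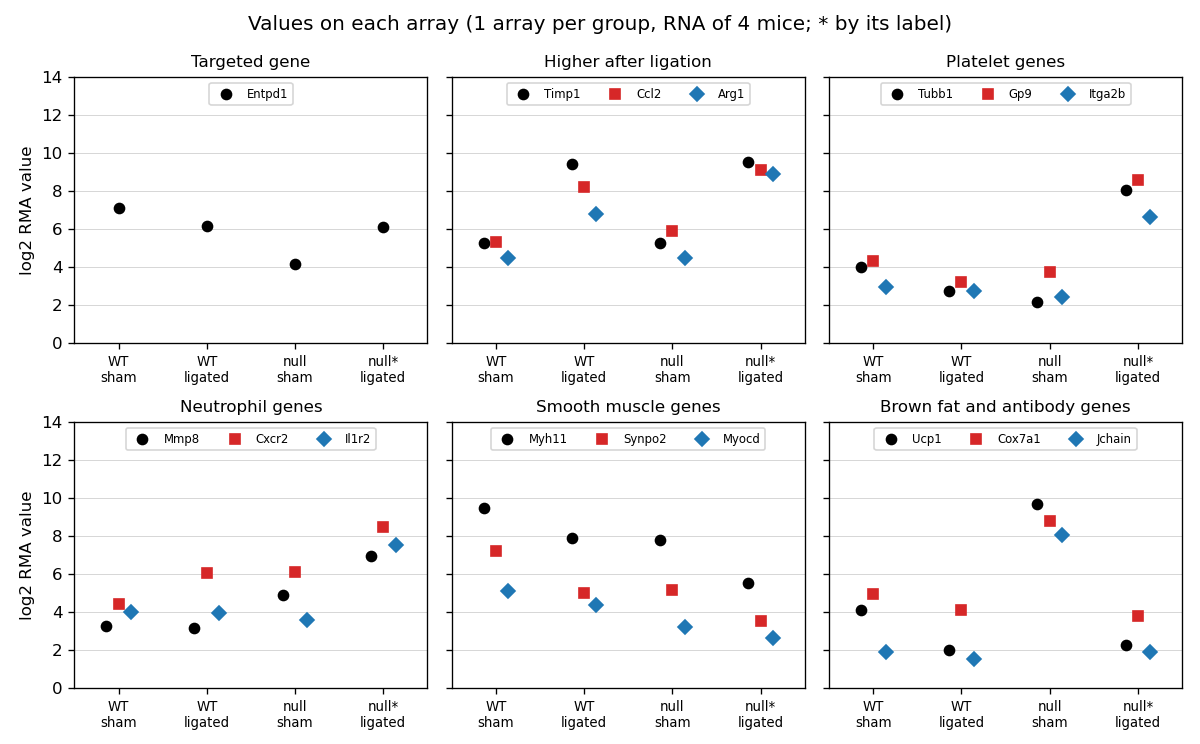
Log2 RMA value (y axis) of named genes on each of the 4 arrays (x axis), with 1 point per gene and array; null* is the array labelled Cd39-null, ligated. Entpd1 was at 4.16 in Cd39-null, sham and between 6.14 and 7.11 on the other arrays, and the platelet gene Tubb1 was at 8.06 on the array labelled Cd39-null, ligated and between 2.20 and 4.02 elsewhere.

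The first comparison asked how 48 h of ligation altered expression in the wild-type vein. Macrophage, matrix, proliferation and chemokine genes were higher after ligation, and platelet, endothelial, contractile and nerve genes were lower. Of the 14115 genes, 1444 (10.2%) differed at least 2-fold, 932 of them higher and 512 lower; after quantile normalisation these were 781 and 619, and after cyclic loess 834 and 567. Among 13915 simulated unchanged genes, 736 (5.29%) were at least 2-fold apart in the simulated wild-type pair with spreads drawn from the fitted prior. With each gene's posterior spread these were 244 (1.75%). The spreads came from the additive fit over all 4 arrays, which counts differences between the genotypes' responses as error. These shares are therefore not chance rates of the wild-type pair itself, and none was computed for the other pairs. Monocyte and macrophage markers had a median log2 difference of 1.91, and 17 of 19 measured members were at least 2-fold higher. Among these were the chemokine receptor Ccr2 (2.82), the scavenger receptor Msr1 (2.70), the arginine-degrading enzyme Arg1 (2.33) and the mannose receptor Mrc1 (2.11). Cell cycle genes had a median of 1.69 with 16 of 21 members at least 2-fold higher. These included the mitotic kinase Bub1 (2.87), Mki67 (2.59), Top2a (2.59) and the spindle protein Tpx2 (2.33). Matrix and matrix remodelling genes had a median of 1.35 with 17 of 24 members higher. They included Timp1, an inhibitor of matrix metalloproteinases (4.16), the matrix glycoprotein Tnc (2.58) and the collagen gene Col1a1 (2.27). Cytokines and chemokines had a median of 0.83 with 8 of 23 members higher, such as the monocyte chemoattractants Ccl7 (3.79), Ccl3 (3.45) and Ccl2 (2.91). Inflammasome genes had a median of 0.86 with 5 of 11 members higher, such as Il1b (1.42) and the pore-forming Gsdmd (1.39). Each of these 5 medians lay above the 99.9th percentile of random lists matched on expression.

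In the same wild-type comparison, platelet and megakaryocyte markers had a median of -0.97, with 5 of 10 members at least 2-fold lower, among them Clec1b (-2.21) and Gp5 (-2.03). The median of 8 Schwann cell and nerve markers was -0.66, with the fatty acid binding protein Fabp7 at -3.72 and Cdh19 at -1.59. Among 20 endothelial markers, with a median of -0.61, 9 were at least 2-fold lower. They included the phosphatase Ptprb (-1.84), the angiopoietin receptor Tek (-1.70), Nos3 (-1.42) and Vwf (-1.34), while the apelin receptor Aplnr was higher (1.66). Smooth muscle contractile genes had a median of -0.46 with 5 of 18 members at least 2-fold lower, among them Synpo2 (-2.18) and the smooth muscle myosin Myh11 (-1.57). Cardiac muscle markers had a median of -0.46, with Actc1 at -3.50 and Tnnt2 at -1.56 and the other members less than 2-fold apart. These 5 medians lay below the 1st percentile of the random lists, the cardiac one only with the filter on dim genes and 1 probe set per gene. No such separation was seen for neutrophil markers (median 0.03), although Csf3r (1.83), Clec4d (1.79) and Cxcr2 (1.67) were at least 2-fold higher, nor for adipocyte markers (0.03) or oxidative metabolism genes (0.21).

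The same question was asked in the knockout with the array labelled Cd39-null, ligated, against Cd39-null, sham. Here cytokine, neutrophil and platelet genes were higher and adipocyte, oxidative metabolism and B cell genes lower. In all, 2355 genes differed at least 2-fold, 1537 higher and 818 lower, so 65.3% were higher; with the arrays quantile normalised this share was 51.4% of 2172, and with cyclic loess 53.9% of 2177. Platelet and megakaryocyte markers had a median of 4.00 and all 10 measured members were at least 2-fold higher. Examples were the platelet tubulin Tubb1 (5.86), the von Willebrand receptor subunit Gp9 (4.81), the podoplanin receptor Clec1b (4.65) and the integrin chain Itga2b (4.22). Cytokines and chemokines had a median of 2.41 with 20 of 23 members higher. Among these were the neutrophil chemoattractants Cxcl2 (5.98), Cxcl5 (4.34) and Cxcl3 (3.39), as well as Ccl3 (5.43), Il6 (4.40) and the prostaglandin synthase Ptgs2 (3.24). Neutrophil markers had a median of 1.76 with 10 of 18 members higher, such as Csf3r (4.54), Trem1 (4.35), the gelatinase Mmp9 (4.22) and Il1r2 (3.93). Monocyte and macrophage markers had a median of 1.43 with 11 of 19 members higher. Arg1 (4.45), Chil3 (4.26), Msr1 (3.78) and Clec4n (3.35) were among these, while Mrc1 (0.37) and Gpnmb (-0.41) were less than 2-fold apart. Matrix genes had a median of 1.41 with 15 of 24 members higher, such as Timp1 (4.27), the protease Adam8 (3.64) and Tnc (3.46). All 5 of these medians were above all 10000 random lists.

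Stress, glycolysis and clotting genes were also higher on the array labelled Cd39-null, ligated, than in Cd39-null, sham. Heme and oxidative stress genes had a median of 1.35 with 10 of 17 members higher, among them the heme-degrading Hmox1 (3.46), the cystine transporter Slc7a11 (3.06) and the glutathione reductase Gsr (2.89). Hypoxia and glycolysis genes had a median of 1.29 with 12 of 20 members higher, including the glucose transporter Slc2a1 (2.78), the oxygen-sensing hydroxylase Egln3 (2.48) and Pkm (2.37). Coagulation and fibrinolysis genes had a median of 1.15 with 12 of 20 members higher. These included F5 (5.01), the thrombin receptor F2rl2 (4.07), F10 (3.49) and Serpinb2 (2.75), of which F5 and F2rl2 are also carried by platelets or megakaryocytes. The 3 medians were above all random lists. Cell cycle genes had a median of 0.75 (percentile 99.7) with 8 of 21 members higher. Tpx2 (1.96) and Bub1b (1.60) were among these, while Bub1 (0.01) and Mki67 (-0.16) were close to their sham value. In Cd39-null, sham, both of the latter were already at least 2-fold above wild type, sham. Immediate early genes had a median of 0.70 (percentile 98.9) with Atf3 at 2.73. Purinergic signalling genes had a median of 0.69 (percentile 99.3), with the ADP receptor P2ry12 at 3.14, the AMP-degrading Nt5e at 2.69 and the UDP receptor P2ry6 at 2.11. Without the dimmer genes their median was 0.24 and did not stand apart. Of the 23 members 18 were measured, Entpd1 itself (1.98) among them, but not Adora1, Adora2a, Adora2b, Adora3 and Enpp1. Platelet markers had a median of 4.00 in this comparison, and whether P2ry12 followed them was not tested.

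On the lower side of this knockout comparison, adipocyte markers had a median of -1.65 with 13 of 17 members at least 2-fold lower, including the brown fat uncoupling protein Ucp1 (-7.45) and the lipid droplet protein Cidea (-3.28). Oxidative metabolism genes had a median of -1.34 with 12 of 19 members lower, including Cox7a1 (-5.00), the mitochondrial coactivator Ppargc1a (-3.07) and Pdk4 (-3.02). B cell markers had a median of -1.25 with 8 of 11 members lower, such as Ms4a1 (-3.89) and Fcer2a (-2.54). T and NK cell markers had a median of -0.77 with 6 of 16 members lower, such as Cd2 (-1.70). Smooth muscle contractile genes had a median of -0.82 with 9 of 18 members lower, among them the integrin chain Itga8 (-3.38), Rgs5 (-2.34) and Myh11 (-2.24). Schwann cell and nerve markers (-0.78, with S100b at -2.84) and fibroblast markers (-0.32, with Fbln1 at -1.36) also lay below the 2.5th percentile; the fibroblast median was inside the random range after either renormalisation. Endothelial markers had a median of 0.21 (percentile 53.3), which became -0.01 after either renormalisation. The reference of this comparison, the Cd39-null, sham array, itself had adipocyte, oxidative metabolism and B cell medians of 1.07, 1.49 and 1.77 against wild type, sham. Its cell cycle median was 0.28 and its endothelial median -0.98, so the knockout values of these lists rest on this reference too. With wild type, sham, as the reference, a choice made after the data were seen, 2273 genes differed at least 2-fold.

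Genes that differed in the same direction in both genotypes were then identified, as the nearest the design offers to a repeat of the ligation experiment. Among the genes higher in both were chemokine, macrophage and matrix genes, and among those lower in both were some smooth muscle contractile and Schwann cell genes. At least 2-fold higher in both were 512 genes and lower in both 204, against 101 and 29.7 for independent lists, and 13 and 25 genes went in opposite directions. Independent lists are a low reference, since genes with a large spread pass 2-fold more often in each pair. Among 13915 simulated unchanged genes, 79 passed in the same direction in both pairs with prior spreads, and 21 with posterior spreads. The log2 differences had a Pearson correlation of 0.517 and a Spearman correlation of 0.520 across genes, which are not independent replicates; the comparisons share no array. The highest mean differences belonged to Ccl3 (3.45 in wild type and 5.43 in the knockout), Timp1 (4.16 and 4.27), the bacterial RNA sensor Tlr13 (3.03 and 4.01), Cxcl5 (2.46 and 4.34) and Arg1 (2.33 and 4.45). They were followed by Ccl7 (3.79 and 2.76), Msr1 (2.70 and 3.78), Csf3r (1.83 and 4.54), the complement receptor C5ar1 (2.35 and 3.92), Ccl2 (2.91 and 3.20), the ribonucleoprotein Nhp2 (3.02 and 3.09) and Il6 (1.69 and 4.40). Of these 12 genes, 3 were at or under the background on a sham array (Ccl3 and Cxcl5 on both, Il6 in wild type), so the size and order of their differences are approximate. The lowest belonged to Cox8b (-3.02 and -6.84), Ucp1 (-2.11 and -7.45), Retnla (-3.35 and -3.67), Actc1 (-3.50 and -3.03) and the transporter Slc10a4 (-3.07 and -2.87). Next came the B cell gene Ms4a1 (-1.91 and -3.89), the ganglionic acetylcholine receptor subunit Chrna3 (-2.41 and -3.35), Ifit3b (-2.24 and -3.50), Inmt (-3.08 and -2.60), the synaptic vesicle gene Syt1 (-3.05 and -2.41), Fmo2 (-1.74 and -3.62) and Lrrn1 (-2.60 and -2.61). The same limit holds for 6 of these 12, with Ucp1 and Ms4a1 at or under the background on both ligated arrays and Chrna3, Ifit3b, Syt1 and Lrrn1 on the array labelled Cd39-null, ligated.

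Members of the gene lists that were at least 2-fold higher in both genotypes numbered 14 of 24 for matrix, 10 of 19 for monocytes and macrophages, 7 of 23 for cytokines and chemokines, 7 of 21 for cell cycle, 5 of 20 for coagulation and 5 of 17 for heme and oxidative stress. Examples were Adam8 (1.43 and 3.64), Mmp19 (1.82 and 2.68), Col12a1 (1.93 and 1.60), the urokinase Plau (2.09 and 2.42), Hmox1 (2.03 and 3.46), the haptoglobin gene Hp (2.63 and 1.67) and Birc5 (2.26 and 1.58). Leukocyte adhesion genes went both ways, with Itgam (2.17 and 3.65), Cd44 (1.36 and 2.83) and Itgb2 (1.24 and 2.38) higher and Jam2 (-1.94 and -1.67) lower; their medians of 0.23 and 0.03 did not stand apart, although in wild type they did without shared members and in the knockout with the mean. Interferon response genes, with medians of 0.15 and -0.22 inside the random range (in wild type above it without a filter), included Ifit3 (-2.07 and -2.61) and Ifit1 (-1.59 and -1.55), lower in both. Lower in both were also 5 of 18 smooth muscle genes and 2 of 8 Schwann cell and nerve genes. Opposite in sign were 9 of 10 platelet genes, 12 of 19 oxidative metabolism genes and 10 of 20 endothelial genes.

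**Figure D2:**
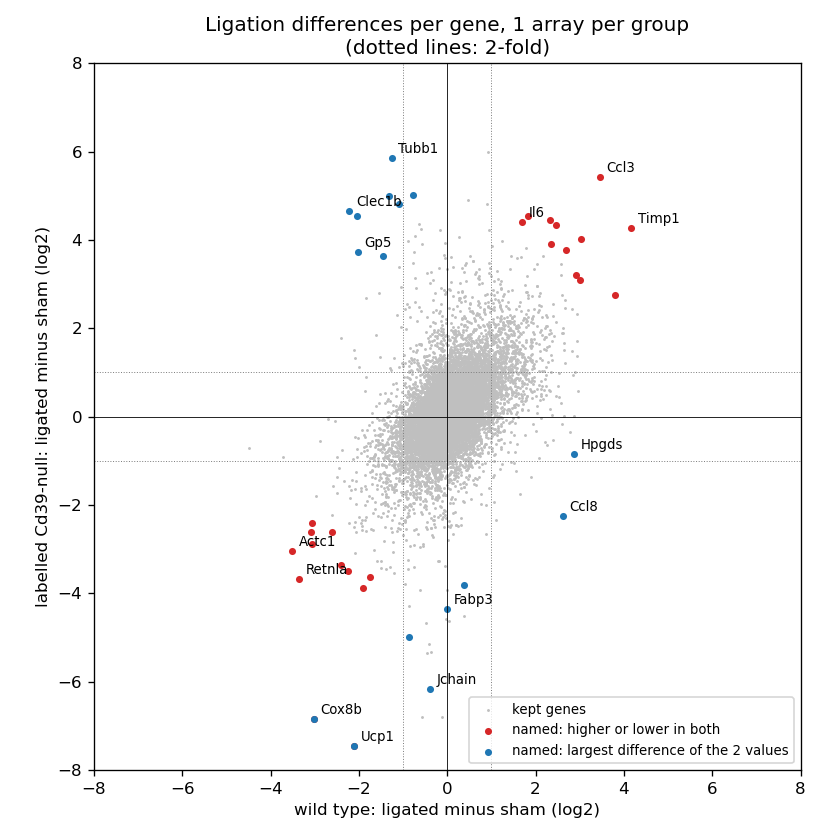
Log2 difference between ligation and sham for each of the 14115 genes in wild type (x axis) and in Cd39-null (y axis, from the array labelled Cd39-null, ligated), with genes named for a mean difference in both genotypes or for the difference between them picked out; Ucp1 and Cox8b belong to both sets. The grey points follow a Pearson correlation of 0.517, Timp1 lies near the diagonal at 4.16 and 4.27, and Tubb1 lies far above it at -1.26 and 5.86.

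With limma's moderated test in an additive model of genotype and ligation, 0 of 14115 genes passed an adjusted p of 0.05 for ligation; 2960 had an unadjusted p under 0.05, 1860 higher and 1100 lower, against about 706 by chance. The smallest adjusted p from limma was 0.0952, shared by Timp1 (mean log2 difference 4.22 ± 0.22 SE), Retnla (-3.51 ± 0.23) and Ccl2 (3.06 ± 0.23) among others. Adjusted over the list alone, limma called 17 of 24 matrix genes, 15 of 23 cytokines and chemokines, 14 of 19 monocyte and macrophage markers, 12 of 21 cell cycle genes, 9 of 20 hypoxia and glycolysis genes, 8 of 20 coagulation genes, 7 of 17 heme and oxidative stress genes, 6 of 18 smooth muscle genes and 5 of 14 leukocyte adhesion genes, against 0 of each adjusted over all genes. The model has 1 residual degree of freedom and counts any difference between the genotypes' responses as error. Genes of a list are not independent and come from the same pools, so the counts over a list alone do not replicate its difference.

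The third comparison set Cd39-null against wild type without ligation. On the Cd39-null, sham array, adipocyte, oxidative metabolism and B cell genes were higher, and contractile, endothelial, platelet and matrix genes were lower. At least 2-fold different were 915 genes (6.48%), 416 higher (45.5%) and 499 lower; after cyclic loess normalisation 58.4% of 849 were higher, so the balance of the directions depended on scaling. B cell markers had a median of 1.77 with 7 of 11 members at least 2-fold higher, among them Cr2 (2.09), Cd79a (2.06) and Ms4a1 (1.99). Oxidative metabolism genes had a median of 1.49 with 14 of 19 members higher, among them Cox7a1 (3.86) and the acyl-CoA dehydrogenase Acadl (2.11). Adipocyte markers had a median of 1.07 with 10 of 17 members higher, including Ucp1 (5.57), Gpd1 (3.21), Cidea (2.76) and Lep (2.48). T and NK cell markers (0.54, with Cd3d at 2.45 and Cd3g at 1.68) and neutrophil markers (0.45, with Retnlg at 1.94 and Cxcr2 at 1.69) were above all random lists too. Cell cycle genes had a median of 0.28 (percentile 99.8), with Mki67 at 2.16, Bub1 at 2.09 and Top2a at 1.73, and monocyte and macrophage markers 0.20 (percentile 98.6), a value that did not stand apart when the mean replaced the median.

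Lower on the same Cd39-null, sham array were smooth muscle contractile genes, with a median of -1.24 and 13 of 18 members at least 2-fold lower. These included Des (-2.18), Synpo2 (-2.01), the contractile coactivator Myocd (-1.89) and Myh11 (-1.68). Endothelial markers had a median of -0.98 with 9 of 20 members lower, such as Eng (-1.44), Tek (-1.24) and Nos3 (-1.24). Platelet markers had a median of -0.85 with 4 of 10 members lower, among them Clec1b (-2.20) and Tubb1 (-1.82). Matrix genes had a median of -0.73 with 9 of 24 members lower, such as Col6a3 (-1.41), Tnc (-1.30) and Postn (-1.10). All 4 medians were at or below the 0.01th percentile of the random lists. The medians of cytokines and chemokines (0.04), hypoxia and glycolysis genes (-0.02), heme and oxidative stress genes (-0.04), coagulation genes (-0.12) and fibroblast markers (-0.23) did not stand apart, although the cytokine one did without the dimmer genes.

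After ligation, the array labelled Cd39-null, ligated, was compared with wild type, ligated. Platelet, neutrophil, cytokine and glycolysis genes were higher on it, and contractile and matrix genes were lower; these directions rest on its label. At least 2-fold different were 885 genes (6.27%), 510 higher and 375 lower; at a 1.5-fold threshold the balance turned, with 1186 higher and 1333 lower. Platelet markers had a median of 4.03 with 9 of 10 members at least 2-fold higher, such as Gp9 (5.33) and Tubb1 (5.30). Neutrophil markers had a median of 2.30 with 15 of 18 members higher. Among these were Trem1 (4.65), the neutrophil collagenase Mmp8 (3.82), Il1r2 (3.57), Csf3r (3.08) and Mmp9 (2.95). Cytokines and chemokines had a median of 1.49 with 13 of 23 members higher, among them Il6 (3.25), Cxcl3 (3.13) and Ptgs2 (2.47). Hypoxia and glycolysis genes had a median of 0.98 with 9 of 20 members higher, including Egln3 (3.00) and Slc2a1 (1.80). Heme and oxidative stress genes had a median of 0.47 with Slc7a11 at 2.63, and coagulation genes one of 0.42 with F5 at 4.81. Each of these 6 medians lay above the 99.9th percentile.

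Lower on the array labelled Cd39-null, ligated, than in wild type, ligated, were smooth muscle contractile genes, with a median of -1.30 and 13 of 18 members at least 2-fold lower, among them Itga8 (-3.56), Myh11 (-2.35) and the potassium channel subunit Kcnmb1 (-2.22). Matrix genes had a median of -0.59 with 7 of 24 members lower, such as Eln (-2.40) and Col1a1 (-1.62), and 2 higher, 1 of them Adam8 (2.17). Monocyte and macrophage markers split, with a median of -0.54, 4 of 19 members higher and 5 lower. Chil3 (3.40), Cd14 (2.13) and Arg1 (2.10) were higher, and Gpnmb (-1.50), Ms4a7 (-1.50) and Mrc1 (-1.35) lower. The mean over these markers, -0.08, did not stand apart. Fibroblast markers (-0.51, with Cd248 at -1.57), adipocyte markers (-0.35), cell cycle genes (-0.31) and oxidative metabolism genes (-0.26, inside the random range after quantile normalisation and with the mean) were also below the 2.5th percentile. The T and NK cell median of 0.11 was at percentile 97.7 and inside the random range without a filter, with the median over probe sets, after quantile normalisation and with the mean, and the endothelial (-0.14) and B cell (0.07) medians did not stand apart, although the endothelial one did without shared members.

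Contractile transcripts were lower by genotype both with and without ligation, and some neutrophil transcripts were higher. At least 2-fold higher in both conditions were 38 genes and lower in both 77, against 15.03 and 13.3 for independent lists, and 15 and 32 genes went in opposite directions. Independent lists are a low reference, since genes with a large spread pass 2-fold more often in each pair. Among 13915 simulated unchanged genes, 79 passed in the same direction in both ligation pairs with prior spreads, and 21 with posterior spreads. The excess over independent lists is thus no measure of a shared genotype effect. The highest mean genotype differences belonged to Mmp8 (1.63 in sham and 3.82 in ligated), the antiprotease Slpi (3.52 and 1.34), Retnlg (1.94 and 2.83) and the ribonuclease RNA Rmrp (1.84 and 2.79), followed by Ifitm6 (2.52 and 1.76), Slfn4 (0.97 and 3.14), Cxcr2 (1.69 and 2.41) and Mcemp1 (0.87 and 3.23). Slfn4 was at or under the background in wild type, sham. The lowest belonged to Tgfb3 (-2.07 and -2.25), the muscle adaptor Pdlim3 (-1.31 and -2.94), the collagen regulator Cthrc1 (-2.30 and -1.95), Ccn3 (-1.20 and -2.89), Fcrls (-0.64 and -3.44), Fndc1 (-1.19 and -2.84), Myh11 (-1.68 and -2.35) and Gpc6 (-1.97 and -1.99), with Ccn3 at or under the background on the array labelled Cd39-null, ligated. Of 18 smooth muscle genes, 9 were at least 2-fold lower in both conditions, and of 18 neutrophil markers, 4 were higher in both, while Mmp9 (-0.31) and Trem1 (-0.33) had negative values in sham. For genotype, limma's additive fit called 0 genes at an adjusted p of 0.05, with 979 at an unadjusted p under 0.05 (322 higher and 657 lower, against 706 by chance) and a smallest adjusted p of 0.667; Tgfb3 had a mean difference of -2.16 ± 0.23 SE. Adjusted over the list alone, limma called 15 of 18 smooth muscle genes, 12 of 24 matrix genes and 6 of 18 neutrophil markers, against 0 of each adjusted over all genes. The p-values are the same in both counts, and only the number of genes adjusted for differs. The genes of a list are not independent and come from the same pools, so such a count does not replicate the list's difference. Across genes, the genotype differences in sham and in ligated veins had a Pearson correlation of 0.106.

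The last comparison was the ligation difference in Cd39-null, which uses the array labelled Cd39-null, ligated, minus that in wild type; with 1 array per group it could not be tested. Platelet genes stood at its upper end and adipocyte and oxidative metabolism genes at its lower end. A difference of at least 1 log2 was found for 1763 genes, 987 positive and 776 negative; this balance turned to 861 and 910 after quantile normalisation and to 837 and 902 after cyclic loess. The highest values were those of Tubb1 (7.12), Clec1b (6.86), the platelet receptor Mpig6b (6.58), the platelet lipoxygenase Alox12 (6.31), Gp9 (5.89), F5 (5.77), Gp5 (5.76) and the platelet chemokine Ppbp (5.08). The lowest were those of the antibody joining chain Jchain (-5.78), Ucp1 (-5.34), the chemokine Ccl8 (-4.87), the fatty acid binding protein Fabp3 (-4.33), the adipocyte gene Arxes1 (-4.20), Cox7a1 (-4.14), Cox8b (-3.82) and the prostaglandin D synthase Hpgds (-3.73). Tubb1, Mpig6b, F5, Jchain, Ucp1 and Arxes1 were at or under the background on at least 1 array, so the size and order of their values are approximate. List medians were 4.95 for platelet, 1.51 for cytokine, 1.18 for neutrophil and 0.97 for endothelial genes, and -0.69 for cell cycle, -0.83 for monocyte and macrophage, -1.69 for adipocyte and -1.77 for oxidative metabolism genes. All 8 lay outside the central 95% of random lists, although the macrophage value was -0.13 and inside it when the mean replaced the median. So did the medians of heme and oxidative stress (0.94), hypoxia and glycolysis (0.92), coagulation (0.71), immediate early (0.46), fibroblast (-0.46), T and NK cell (-0.57) and B cell (-1.54) genes. Such values also hold what set the sham arrays apart. Endothelial genes, for 1, had genotype medians of -0.98 in sham and -0.14 in ligated veins.

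**Figure D3:**
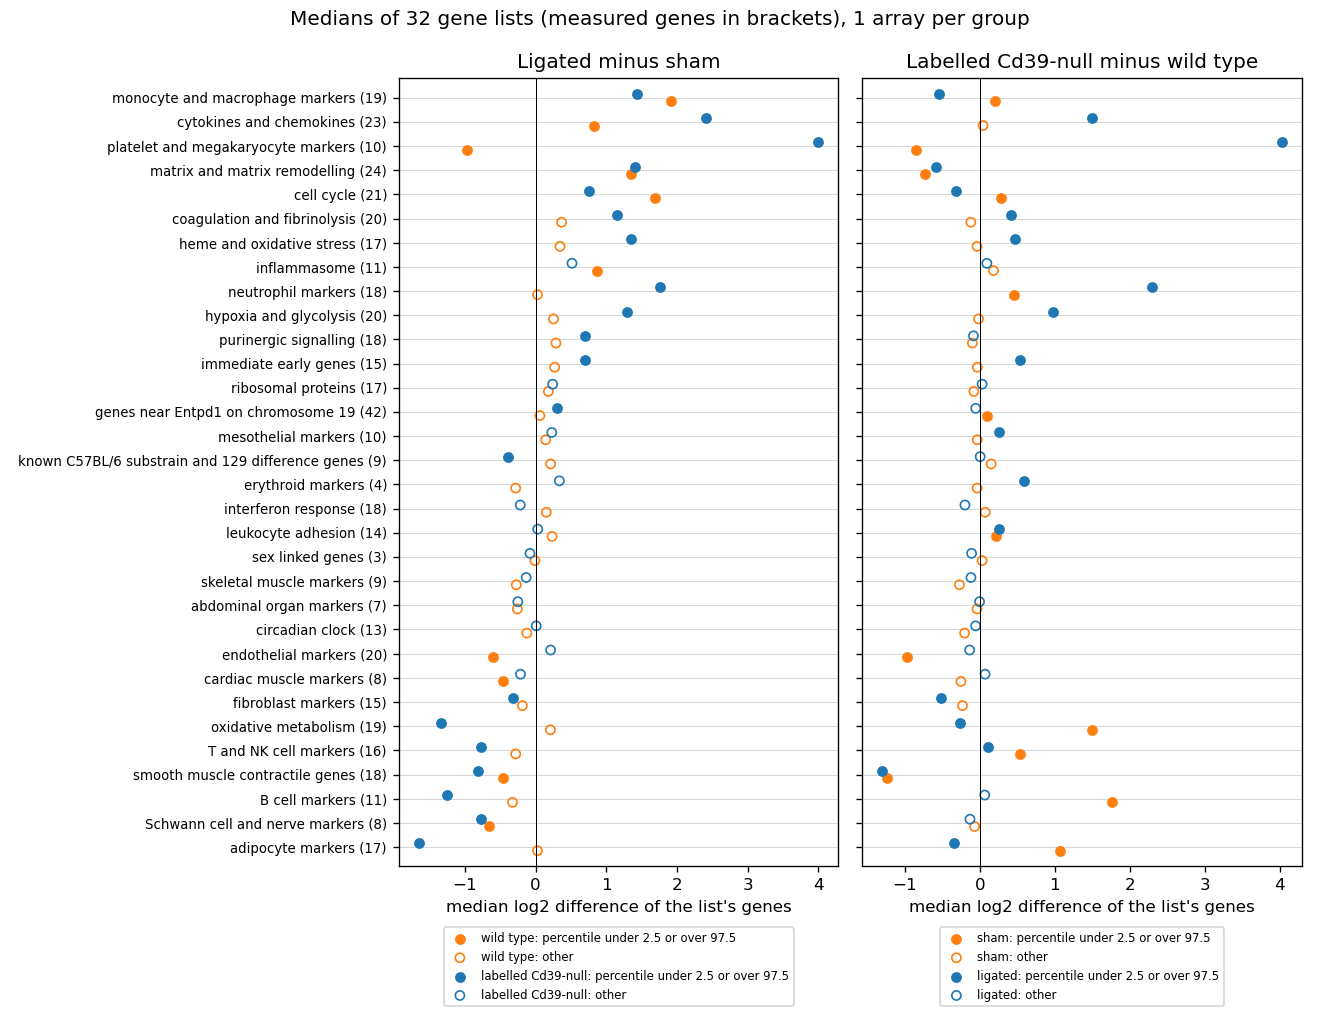
Median log2 difference (x axis) of each fixed gene list (y axis, with the number of measured genes) between ligation and sham in both genotypes (left) and between the genotypes in sham and ligated veins (right), the latter and the knockout values using the array labelled Cd39-null, ligated; filled points lie outside the central 95% of random lists, and genotype values of some lists are given only here. Platelet markers are at -0.97 in wild type and 4.00 in Cd39-null on the left, and smooth muscle genes are at -1.24 and -1.30 on the right.

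By genotype in ligated veins, some further lists stood apart, in comparisons that rest on the label of the array labelled Cd39-null, ligated. The 4 erythroid markers had a median of 0.58 (percentile 99.6), with Alas2 at 2.48 and the others less than 2-fold apart. Immediate early genes had one of 0.53 (above all random lists), leukocyte adhesion genes 0.26 (percentile 98.3, and 0.21 at percentile 98.0 in sham) and mesothelial markers 0.25 (percentile 99.5). The leukocyte adhesion value in ligated veins did not stand apart without members shared with another list, and that in sham and the mesothelial value did not with the dimmer genes left out or with the mean. For the other fixed lists, medians after ligation in wild type and in the knockout were 0.18 and 0.24 for ribosomal proteins, -0.13 and 0.01 for circadian clock genes and 0.14 and 0.23 for mesothelial markers. They were -0.27 and -0.13 for skeletal muscle markers, -0.26 and -0.25 for abdominal organ markers and -0.28 and 0.34 for the erythroid markers, all inside the random range. In wild type the coagulation (0.37), heme and oxidative stress (0.34), purinergic (0.29), immediate early (0.27) and hypoxia (0.25) lists and the T and NK cell (-0.28), B cell (-0.33) and fibroblast (-0.19) lists did not stand apart either. The same held for the inflammasome (0.51) and cardiac (-0.21) lists in the knockout. Some of these depended on the setting: in wild type the heme list stood apart without the dimmer genes, after either renormalisation and with the mean, the coagulation and B cell lists with the mean, the T and NK cell list with the mean or without the dimmer genes, and the skeletal list without a filter. In the knockout the cardiac list did with the mean or without the dimmer genes, and the inflammasome list with the mean or without shared members. Within these lists some members were at least 2-fold different in both genotypes, such as Egr2 (1.36 and 1.59), Rps9 (1.55 and 1.03), Wt1 (1.26 and 1.25), Gpm6a (-1.64 and -1.39) and Alb (-1.19 and -1.07). For 42 genes near Entpd1 on chromosome 19 the median genotype difference was 0.09 in sham (percentile 98.0, which 3 alternatives moved inside the random range) and -0.05 in ligated. Of these 42 genes, 1 gene, Blnk (1.72), was at least 2-fold different in sham, and 2 were at least 2-fold lower by genotype in ligated veins. The ligation medians of the 42 genes were 0.06 in wild type and 0.30 in the knockout, the latter at percentile 99.2 but inside the random range under 5 alternatives. Genes known to differ among C57BL/6 substrains and related strains had genotype medians of 0.15 and 0.01 and ligation medians of 0.21 and -0.39, the latter at percentile 2.12 but inside the random range under 6 alternatives, and none of the 9 was at least 2-fold different between the genotypes. The 3 kept sex linked genes had ligation medians of -0.01 and -0.08. The Y-linked Eif2s3y, Kdm5d and Uty had log2 values between 5.59 and 6.17, 4.91 and 5.11, and 4.35 and 4.56 over the 4 arrays, and Xist was between 1.58 and 1.91, below the expression filter. The Y-linked genes lay above the olfactory receptor background on each array, so each pool held male RNA. Xist lay under that background on each array and gave no sign of female RNA. No array from known females was there to show how its probe set reads.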

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

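The 3 patterns weighed here were noticed in these data before any test of them was devised, and the exchange of the ligated arrays' labels and the platelet level in sham veins were tests chosen only after their own values had been seen. Pf4 and the genes of the added platelet, brown adipocyte and plasma cell lists are named after their values were seen. Results are listed because ligation differed in opposite directions in the genotypes or genotype did in sham and ligated veins, with 1 array per group, or because probe sets outside the gene comparisons held a signal. Each difference of ligation differences in this part is untested and depends on the label of the array labelled Cd39-null, ligated. The SE of a list's median in this part comes from resampling genes within 1 pair of arrays. It holds no spread between arrays, pools or mice, so limits met or missed by it describe these arrays only.

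Entpd1 differed by -0.94 log2 after ligation in wild type and by 1.98 in the knockout, a difference of 2.92 that was not tested. An exchange of labels between the ligated arrays would not account for it, since the array labelled wild type, ligated, also lay 2.01 log2 above Cd39-null, sham, although this value leaves open whether labels were exchanged, and a smaller share of vessel wall cells in the Cd39-null, sham piece is argued against as the whole reason for its low Entpd1, since Entpd1 differed there by -2.95 log2 and the lowest of 38 endothelial and smooth muscle genes, Des, by -2.18. Wild-type RNA on the array labelled Cd39-null, ligated, may be present: of 32 genes within 10 Mb of Entpd1 that differed at least 1.5-fold in sham, 46.9% kept their sign in ligated veins (exact 95% interval 29.1% to 65.3%) against 58.0% of 3157 genes elsewhere. This decides nothing, because such genes were no more frequent near Entpd1 (21.9%) than elsewhere (22.6%), so no linked differences were there to follow. A response of Cd39-null veins to ligation, with the probe set reading transcript outside the disrupted part of the gene, stays open and was not tested.

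Platelet and megakaryocyte markers differed in opposite directions after ligation in the genotypes, with an untested difference of 4.95 log2 in the list's median, as did Tubb1 (7.12), Clec1b (6.86), Mpig6b (6.58), Alox12 (6.31), Gp9 (5.89), F5 (5.77), Gp5 (5.76) and Ppbp (5.08). Renormalising the deposited values did not remove the pattern. The list's median genotype difference in ligated veins was at least 3.94 (SE 0.53) after quantile or cyclic loess normalisation. RMA had already quantile normalised these arrays, so little change could follow. The authors' own RMA step was not tested by this. A genotype difference that needs no ligation was not seen in sham, where the list's median was -0.85 (SE 0.36). This does not exclude one, since it rests on 1 pair of arrays. Endothelial (-0.98) and smooth muscle (-1.24) medians were lower in that pair too, so the platelet value may reflect what the sham pieces held. Platelets or clot in the piece labelled Cd39-null, ligated, remain a candidate explanation. By genotype in ligated veins, 15 further platelet genes had a median of 1.23 (SE 0.53), from 2.86 for Rgs18 to 0.084 for Slc35d3. Red cell genes were mixed, with a median of 0.58 for 4 erythroid markers and differences of 0.13 to 0.29 for 4 hemoglobin probe sets. Against Cd39-null, sham, these probe sets were at -0.64 to -0.38 on the array labelled Cd39-null, ligated. The markers with the highest readings, which are not comparable between probe sets, were Ppbp and Pf4, at 9.33 and 9.18 log2 on that array and already at 8.79 and 7.96 in wild type, sham, where all 10 markers and 13 of the 15 further genes lay above the olfactory receptor background, and 0 of them were in another list. An effect of genotype on the clot after ligation stays open and was not tested.

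Adipocyte markers and oxidative metabolism genes were higher by genotype in sham and had medians of -0.35 and -0.26 in ligated veins, where 1 of 17 and 0 of 19 were at least 2-fold lower and the oxidative median was inside the random range after quantile normalisation and with the mean; the untested differences were -1.69 and -1.77 log2, and immunoglobulin genes had a median genotype difference of 4.72 in sham and 0.18 in ligated. A genotype difference that needs no sham surgery stays open: the median of 10 further brown adipocyte genes in ligated veins was -0.030 (SE 0.17), which decides nothing, because the limit set for it overlooked that the same genes might hardly differ in sham and the label of the ligated array is in doubt. Brown fat on the Cd39-null, sham piece was not decided by those genes. Their median in sham was 0.34 (SE 0.31), less than 1 SE under the limit of 0.5 set for excluding it. Fabp3 was at 4.12, Letmd1 at 1.58 and Kcnk3 at -0.72. Antibody-secreting cells there were not decided by their added list either. Its 13 plasma cell genes had a median of 0.96 (SE 0.20), within 1 SE of the limit of 1 set for them. Mzb1 was at 1.99, Slamf7 at 1.75 and Sdc1 at -1.56. Both limits concern the added lists alone. Genes seen earlier were not part of them: 14 of 16 immunoglobulin genes were at least 2-fold higher in sham, the B cell median was 1.77 and Ucp1 differed by 5.57. Of the added lists, 7 brown adipocyte and 8 plasma cell genes lay above background in wild type, sham, too. An effect of genotype in sham veins stays open and was not tested.

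Monocyte and macrophage markers had median genotype differences of 0.20 in sham and -0.54 in ligated veins, an untested difference of -0.83 log2, but their members split and the means (0.050, -0.080 and -0.13) did not stand apart. Cell cycle genes had medians of 0.28 and -0.31, an untested difference of -0.69, with 4 of 21 members at least 2-fold higher in sham and 0 lower in ligated. Slpi differed by 1.57 after ligation in wild type and by -0.61 in the knockout, an untested difference of -2.19. Ccl8 differed by 2.62 and -2.25, an untested difference of -4.87, and Hpgds by 2.88 and -0.85, one of -3.73. Of 14338 probe sets with no gene symbol or several, which lie outside the 14115 genes compared, 448 were at least 2-fold higher after ligation in both genotypes and 163 lower in both, against 101 and 47.4 if the genotypes were independent, and 378 and 142 of them had no symbol. Independence is a low reference here too, since probe sets with a large spread pass 2-fold more often in each pair.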

How the results depend on the processing

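The tests with another reference array and those without genes of fat, immunoglobulins, B and plasma cells or of platelets and neutrophils were chosen only after the results had been seen. Under the alternatives that kept the 2-fold threshold, each count stayed within 1.5 times its value. With a 1.5-fold threshold, which admits more genes by construction, counts were 3896 (ligation, wild type), 5145 (ligation, knockout), 3192 (genotype, sham), 2519 (genotype, ligated) and 4448 (difference of ligation differences). Knockout ligation gave 2273 genes against wild type, sham, 2293 without genes of fat, immunoglobulins, B and plasma cells, and 2326 without platelet and neutrophil genes. limma called 0 genes for ligation under its 8 alternatives, with smallest adjusted p from 0.0754 to 0.213 and 2300 to 5525 genes at an unadjusted p under 0.05, and 0 for genotype under 9, with 0.593 to 0.850 and 717 to 2042. The correlation of ligation differences was 0.493 to 0.528. Entpd1's knockout ligation difference was 1.72 after quantile normalisation. Values of named genes moved in 50 cases, did not in 2574, and 0 reversed. A value counted as moved if it shifted by more than the gene's SE in the additive fit. That SE is wide where the genotypes' responses differed, such as 1.66 log2 for Tubb1 and 1.26 for Ucp1. For members of lists, a change of sign counted as reversed only where the main value was at least 1 log2 in size. The tally is therefore a lenient one. Of 122 list values, 76 stood apart, 62 of them under each alternative run; for those that crossed the limit the cause was not tested. Without a filter, T and NK cell (0.091, genotype, ligated), cardiac (-0.37, wild-type ligation), near Entpd1 (0.054, genotype, sham) and strain difference genes (-0.067, knockout ligation) no longer stood apart, near Entpd1 reversed (-0.00055, knockout ligation), and skeletal muscle (-0.38) and interferon (0.33) newly stood apart in wild-type ligation. At the 50th percentile filter, purinergic (0.24), near Entpd1 (0.32) and strain difference genes (-0.049) in knockout ligation, near Entpd1 (0.071) and leukocyte adhesion (0.21) by genotype in sham and mesothelial (0.36, genotype, ligated) no longer did; cardiac (-0.81, knockout ligation), T and NK cell (-0.72) and heme (0.53, both wild-type ligation) and cytokines (0.15, genotype, sham) newly did. With the median over probe sets, T and NK cell (0.11, genotype, ligated) and cardiac (-0.37, wild-type ligation) no longer did. After quantile normalisation, T and NK cell (0.11) and oxidative metabolism (-0.25) by genotype in ligated and fibroblast (-0.41), near Entpd1 (0.10) and strain difference genes (-0.24) in knockout ligation no longer did, and heme did in wild-type ligation (0.33). After cyclic loess, fibroblast (-0.38), near Entpd1 (0.13) and strain difference genes (-0.24) in knockout ligation no longer did, and heme did in wild-type ligation (0.39). With list means, macrophage genes by genotype in sham (0.050), in ligated (-0.080) and in the difference (-0.13), T and NK cell (0.15), mesothelial (0.17) and oxidative metabolism (-0.21) by genotype in ligated, near Entpd1 in knockout ligation (0.11) and by genotype in sham (0.091) and leukocyte adhesion by genotype in sham (0.073) no longer did, and strain difference genes reversed in knockout ligation (0.015). Means newly apart were T and NK cell (-0.34), B cell (-0.36), coagulation (0.48) and heme (0.53) in wild-type ligation, and cardiac (-0.59), leukocyte adhesion (0.73) and inflammasome (0.79) in knockout ligation. Without shared members, strain difference genes (-0.046, knockout ligation) and leukocyte adhesion (0.18, genotype, ligated) no longer did, and endothelial (-0.23, genotype, ligated), leukocyte adhesion (0.44, wild-type ligation) and inflammasome (0.79, knockout ligation) newly did. No array could be left out, since no residual degree of freedom would remain. Background, with 95th percentiles of 2.66 to 2.97 log2, limits what dim genes can show.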

Other observations

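Immunoglobulin genes were low on 3 arrays and high on the Cd39-null, sham array, and were singled out after their values were seen. Igkc was at 2.93 in wild type, sham, 2.57 in wild type, ligated, 7.84 in Cd39-null, sham and 2.53 on the array labelled Cd39-null, ligated, and Igha at 3.46, 3.47, 8.27 and 4.35. Of 16 measured immunoglobulin genes, 14 were at least 2-fold higher by genotype in sham and 1 in ligated, and the median genotype difference in sham was 4.72 as deposited and 4.80 after quantile or cyclic loess normalisation. All 16 were at least 2-fold lower on the array labelled Cd39-null, ligated, than in Cd39-null, sham.

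Of 43 genes of small nuclear, nucleolar and related RNAs, also singled out after their values were seen and not set against random lists, 5 were at least 2-fold higher by genotype in both surgeries and 0 lower in both. Rnu3a, an RNA of ribosome assembly, differed by 2.85 log2 in sham and by 2.51 in ligated veins, and Snord49b by 2.57 and 1.85. Over the 43 genes the medians were 0.34 and 0.40, and they were 0.35 and 0.37 after quantile and 0.41 and 0.42 after cyclic loess normalisation. Probe sets shared by several hemoglobin genes read between 9.84 and 11.1 log2 on the 4 arrays, at or above the 99.7th percentile of each.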
